A study of Mus musculus with 9 samples.

How the data were processed

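The study measured polyadenylated RNA in 9 libraries of mouse leukemia stem cells from C57BL/6 mice with AML, 3 untreated, 3 given IFN-γ at 10 ng/ml and 3 co-cultured with ILC1s, each for 3 days. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, LSCs were re-sorted by flow cytometry after culture, cDNA was made from total RNA with the SMART-Seq v4 low-input kit, sheared and built into libraries, and sequenced as single reads of 51 cycles with no strand information. The gates of the sort are not given in the sources used here.

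The authors deposited 1 table of whole-number read counts per gene symbol, with a chromosome, start, end and strand for each gene and 1 column per library, without normalization. Per the submitters' processing notes, the tools were bcl2fastq 2.18.0.12, STAR 2.6.0, HTSeq 0.6.0 and edgeR 3.28.1, and the builds were hg19 and mm10, with no role given for each. The samples are mouse, and 23325 symbols matched a RefSeq annotation of GRCm38.p6 (the assembly behind mm10) on the same chromosome, 69.8% of them with both ends within 100 bases, so the coordinates are read as mm10 and are printed as deposited. Which annotation was used to count reads is not given in the sources used here. HTSeq leaves out reads that fit more than 1 gene, and unstranded reads cannot tell a gene from an antisense or overlapping partner, so genes with near-identical copies and overlapping genes are uncertain. SMART-Seq amplifies cDNA without molecular identifiers, so reads are not independent molecules and counting intervals cover counting error only.

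The table held 24091 genes, of which 1924 had 0 counts in all libraries. Library totals ran from 28305753 to 39447594 counts. The counts of replicate pairs differed by more than sampling noise (chi-square per degree of freedom 9.85 to 16.4), so no library appears to have been deposited more than once. A gene with 0 counts was given a floor of 3 counts over the 3 libraries of a group, and ratios from few counts have exact 95% intervals.

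Differential expression was tested on the counts with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr (13406 genes kept), a quasi-likelihood fit with robust dispersions over all 9 libraries with group means, and F tests for the 3 comparisons, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log CPM used a prior count of 2. Standard errors of log2 fold changes come from the same fits. On simulated counts with 200 changed genes, edgeR recovered 64.2%, 77.6% and 86.4% of genes changed by 0.5, 1 and 2 on the log2 scale for IFN-γ against untreated, and called 4 unchanged genes among 13144 run. For co-culture against untreated the shares were 46.3%, 62.7% and 78.8% with 13 unchanged genes called, and for co-culture against IFN-γ 55.2%, 59.7% and 74.2% with 6, among 13134 genes run.

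Gene lists (33, with 1006 different genes, 866 of them tested) were fixed before the data were examined. Some genes, such as Atf3 and Tnfsf10, are on more than 1 list, so the list results are not independent of each other. The list of mitochondrially encoded transcripts had no gene among those tested and was left out, so 32 lists were tested. They covered the IFN-γ response, type I interferon-stimulated genes, MHC class I and II, stem cell and MLL-type leukemia genes, granulocyte, monocyte and macrophage, dendritic cell, lymphoid, ILC1 and NK cell, T cell, mature B cell, erythroid, megakaryocyte and mast cell genes, S phase, G2/M, p53 targets, cell death, JAK-STAT, PI3K-AKT-mTOR, MYC targets, oxidative phosphorylation, glycolysis and hypoxia, cholesterol biosynthesis, the unfolded protein and ATF4 response, immediate early and heat shock genes, NF-κB and inflammatory genes, checkpoint and NK-ligand genes, adhesion and homing receptors, ribosomal proteins and histones. Each list was tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. On simulated data 0 of 30 unshifted lists were called in each comparison. This sets no error rate for lists whose genes vary together, such as the type I interferon-stimulated list (estimated correlation 0.52).

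Named genes followed a rule fixed before the data were examined: per comparison the 12 largest rises and 12 largest falls among called genes of average log2 CPM of at least 3 whose groups did not overlap, passing over predicted gene models and lymphocyte markers; up to 4 called members per list with the smallest p, or, with none called, up to 2 of the highest CPM; and 22 genes fixed by name. Not every gene the rule took is printed. Genes outside it are said to be named after their values were seen, or to be outside the naming rule.

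The overlap of the treatment responses was set against 100 simulated data sets in which both treated groups were unchanged. Alternatives fixed before the data were examined were DESeq2's relative log expression size factors, library totals alone, no count filter, a stricter filter, DESeq2 1.42.0, limma-voom, a fit without robust dispersions, a fit of the 2 compared groups alone, the replicate number as a block, and leaving out each library in turn. Counting only genes of average log2 CPM of at least 2 was added after the data were seen. Each comparison was also rerun for the 10 ways to split its 6 libraries.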

Results

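Messenger RNA was measured in leukemia stem cells (LSCs), the self-renewing fraction of an acute myeloid leukemia (AML), taken from the spleens of leukemic mice that carry a partial tandem duplication in Mll and an internal tandem duplication in both copies of Flt3. The cells were kept for 3 days in medium with the growth factors SCF, TPO, Flt3-L, IL-3 and IL-6. They were left untreated, given interferon-γ (IFN-γ) at 10 ng/ml, or grown together with type 1 innate lymphoid cells (ILC1s), tissue-resident lymphocytes known to secrete IFN-γ. LSCs were sorted again before RNA was isolated. Each of the 3 groups held 3 libraries. Rounded, the counts over all genes summed to 31802600, 33814600 and 28305800 in the untreated libraries. They summed to 38230100, 32412200 and 37391000 with IFN-γ, and to 37693800, 36156300 and 39447600 after co-culture. The series set out to find which LSC pathways ILC1s and IFN-γ act on. Levels below are CPM, counts divided by the library size after scaling by trimmed mean of M values (TMM), as mean ± SD of 3 libraries. Changes are log2 fold changes ± SE from edgeR's quasi-likelihood fit with n = 3 libraries per group, and a gene is said to rise or fall at a Benjamini-Hochberg adjusted p under 0.05. The labels do not say whether the libraries of a group came from separate mice or cultures, so these p-values measure only the spread between these samples, which may be technical.

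The untreated libraries lay apart from both treated groups on the principal component that held 49.6% of the variance, with scores of -51.0, -53.5 and -56.1 against 16.5 to 37.0 in the 6 treated libraries. Of the 24091 genes in the table, 13406 had enough counts to be tested. The untreated LSCs expressed both chains of the IFN-γ receptor, Ifngr1 at 92.8 ± 10.5 CPM and Ifngr2 at 102 ± 5.31 CPM. The untreated cells also expressed the progenitor genes Kit (218 ± 21.1 CPM) and Cd34 (542 ± 15 CPM) and the granule enzyme Mpo (10880 ± 1180 CPM). Ifng itself was close to absent from the untreated libraries, with 3 counts summed over them, and reached 15 counts in the IFN-γ libraries and 12975 counts in the co-culture libraries.

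With IFN-γ alone, the largest rises among annotated genes of an average log2 CPM of at least 3 included interferon-inducible GTPases, chemokines and antigen presentation factors. Iigp1, a GTPase that acts on pathogen vacuoles, rose from 1.5 ± 2.02 to 733 ± 116 CPM (log2 fold change 8.92 ± 0.58), and Gbp4 and Gbp2, guanylate-binding proteins, rose by 8.44 ± 0.56 and 7.20 ± 0.27. The folds of Iigp1 and Gbp4 rest on untreated 1, without which they were 11.13 and 10.78. The chemokines Cxcl9 (6.93 ± 0.56) and Cxcl10 (6.15 ± 0.33), which attract T cells and NK cells, rose as well, as did the nucleic acid sensor Zbp1 (6.26 ± 0.30). Stat1, the transcription factor downstream of the IFN-γ receptor, rose from 71.8 ± 6.38 to 2013 ± 251 CPM (4.81 ± 0.12, edgeR quasi-likelihood adjusted p = 4.6e-11). Irf1 (3.13 ± 0.11), Irf8 (2.39 ± 0.11) and the feedback inhibitor Socs1 (2.06 ± 0.07) rose with it.

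Of the 45 genes of the IFN-γ response list, 43 rose and 0 fell (44 adjusted over the list alone, camera adjusted p = 7.6e-49). Irgm2 (3.80 ± 0.08), Ifi47 (3.01 ± 0.07) and Gbp3 (4.06 ± 0.11) had the smallest p-values among the annotated genes of that list. In the deposited mm10 coordinates Stat1 lies on chromosome 1 from 52119438 to 52161865 (+ strand), Iigp1 on chromosome 18 from 60376029 to 60392629 (+ strand) and Irf1 on chromosome 11 from 53770014 to 53778374 (+ strand). All 42 genes of the type I interferon-stimulated list rose (42 adjusted over the list alone, camera adjusted p = 7.6e-34), with a median log2 change of 3.45. For this list the adjusted p was 0.0829 with an estimated correlation. Bst2 (2.06 ± 0.10), Ifi204 (2.37 ± 0.14) and Oas1a (2.13 ± 0.13) were among them. Reads of near-identical family members (the Gbp, Ifit3, Oas1, Ms4a and H2 genes and the Irg GTPases Iigp1, Irgm2 and Ifi47) can be shared between copies at this read length, so single values in these families are uncertain.

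Antigen presentation genes rose in both classes. Of 23 genes of the MHC class I list, 22 rose and 0 fell (22 adjusted over the list alone, camera adjusted p = 4.1e-30), led by the immunoproteasome subunit Psmb9 (2.48 ± 0.05) and the peptide transporter Tap1 (2.95 ± 0.07). Of 15 genes of the MHC class II list, 10 rose and 0 fell (10 and 1 adjusted over the list alone, camera adjusted p = 1.1e-11). H2-Eb1, a class II chain on chromosome 17 (34264832 to 34316674, + strand), rose from 6.74 ± 1.10 to 284 ± 21.6 CPM (5.39 ± 0.12), and the class II transactivator Ciita rose by 4.40 ± 0.18. The checkpoint ligand Cd274 (PD-L1; chromosome 19, 29367438 to 29388094, + strand) rose from 17.8 ± 4.49 to 47.7 ± 2.02 CPM (1.43 ± 0.15). In the list of immune checkpoint and NK-ligand genes, 8 of 30 rose and 6 fell (9 and 6 adjusted over the list alone), and the list was not called (camera adjusted p = 0.60). Tnfrsf14 rose by 1.63 ± 0.15 there, while Cd48, a ligand of the NK receptor 2B4, fell by 1.21 ± 0.07.

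Stem cell and progenitor genes fell more often than they rose. Of 43 genes on the list of stem cell and MLL-type leukemia genes, 17 fell and 4 rose (18 and 5 adjusted over the list alone, camera adjusted p = 0.0014), and the adjusted p was 0.0829 with an estimated correlation. Cd34 (chromosome 1, 194938821 to 194961292, + strand) fell from 542 ± 15 to 330 ± 16.3 CPM (-0.72 ± 0.08), and Meis1, a homeobox partner of Hoxa9 in MLL leukemia, fell from 80.0 ± 4.99 to 50.3 ± 1.99 CPM (-0.67 ± 0.07). Sox4 (-0.86 ± 0.06), Adgrg1 (-0.61 ± 0.06) and Hoxa9 (-0.47 ± 0.10) fell too. The 4 that rose were Ly6a, which encodes Sca-1 and is itself interferon-inducible (3.86 ± 0.16), Lmo2 (0.71 ± 0.07), and Cd93 and Clec12a, the last pair named after their values were seen. Flt3 was low throughout and went from 1.71 ± 0.662 to 0.481 ± 0.201 CPM (-1.81 ± 0.46, edgeR adjusted p = 0.014), a call lost without untreated 1 (adjusted p = 0.0662) or without IFNg 2 (adjusted p = 0.0559). Kit (0.20 ± 0.08), Myc (0.02 ± 0.06), Mpo (0.19 ± 0.11), Cebpa (0.08 ± 0.09), Mki67 (-0.09 ± 0.09), Il7r (-1.24 ± 0.68) and Ifngr1 (-0.05 ± 0.07) did not pass the test, and Kit passed it without untreated 2 (adjusted p = 0.0204) or IFNg 3 (adjusted p = 0.0320) and with no count filter (adjusted p = 0.0445). Ifngr2 changed by 0.26 ± 0.07 (edgeR adjusted p = 0.022), a call lost without untreated 2 (adjusted p = 0.0689) or IFNg 2 (adjusted p = 0.0659), and with scaling by library totals (adjusted p = 0.0863).

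Myeloid differentiation genes went both ways. Of 29 genes of the monocyte and macrophage list, 16 rose and 2 fell (17 and 3 adjusted over the list alone, camera adjusted p = 9.8e-06), and the adjusted p was 0.0566 with an estimated correlation. Mpeg1, a macrophage pore-forming protein, rose from 4.74 ± 0.784 to 60.5 ± 11.6 CPM (3.68 ± 0.23), and Ms4a6c (2.77 ± 0.14) and the receptor Tlr2 (1.25 ± 0.08) rose; Adgre1 and Nr4a1 fell, Adgre1 being named after its value was seen. The transcription factor Spi1 (PU.1) rose by 0.28 ± 0.06. In the granulocyte list 4 of 22 genes rose and 5 fell (4 and 7 adjusted over the list alone), and the list was not called (camera adjusted p = 0.61). The neutrophil proteins S100a8 (-2.94 ± 0.23) and Chil3 (-2.66 ± 0.22) fell, and S100a9 fell from 14.2 ± 1.87 to 0.340 ± 0.0310 CPM (-5.37 ± 0.23); Csf3r and Anxa1 fell too, and Mmp8, Ms4a3, Lyz2 and Itgam rose, of which Csf3r, Anxa1, Ms4a3 and Itgam were named after their values were seen. Lysozyme Lyz2 rose by 1.07 ± 0.06.

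Cell death genes rose: 20 of 41 on the list of cell death machinery, with 1 fall, Casp6, named after its value was seen (25 and 2 adjusted over the list alone, camera adjusted p = 5.4e-10). These included the inflammatory caspase Casp1 (1.68 ± 0.07), its adaptor Pycard (1.21 ± 0.07), the necroptosis effector Mlkl (1.48 ± 0.07) and the death ligand Tnfsf10 (3.09 ± 0.19). The death receptor Fas rose by 0.85 ± 0.13. Among 33 JAK-STAT components, 16 rose and 3 fell (17 and 3 adjusted over the list alone, camera adjusted p = 9.8e-06; adjusted p = 0.0566 with an estimated correlation); Jak3, Stat4 and Socs2 were the falls, named after their values were seen. Of 35 NF-κB and inflammatory genes, 15 rose and 5 fell (16 and 5 adjusted over the list alone, camera adjusted p = 0.0015; adjusted p = 0.0566 with an estimated correlation). Csf1 (2.85 ± 0.11) and Tnfaip3 (1.34 ± 0.11) rose, while Traf1 fell by 1.03 ± 0.26, as did Nfkb1, Cxcl3, Cd83 and Ccl17, named after their values were seen. Beyond the lists, S100a4, the nucleoside transporter Slc28a2 (-1.66 ± 0.14) and the endothelial-type receptor Adgrl4 (-1.55 ± 0.12) were among the largest falls of genes with an average log2 CPM of at least 3.

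In all, 2499 genes changed with IFN-γ by edgeR's quasi-likelihood test, 1562 higher and 937 lower (62.5% higher), of which 399 rose and 186 fell at least 2-fold. The 3 IFN-γ libraries did not overlap the 3 untreated ones for 33.5% of the genes, against 10% by chance. With scaling by library totals alone the split became 1142 higher and 2184 lower, or 34.3% higher, so the balance of small changes depended on the scaling; without IFNg 1 or 3 the falls numbered 493 and 506 and the rises 1175 and 1293. The camera calls of 4 of the 32 lists held with an estimated correlation: the IFN-γ response, MHC class I, MHC class II and cell death lists.

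**Figure D1:**
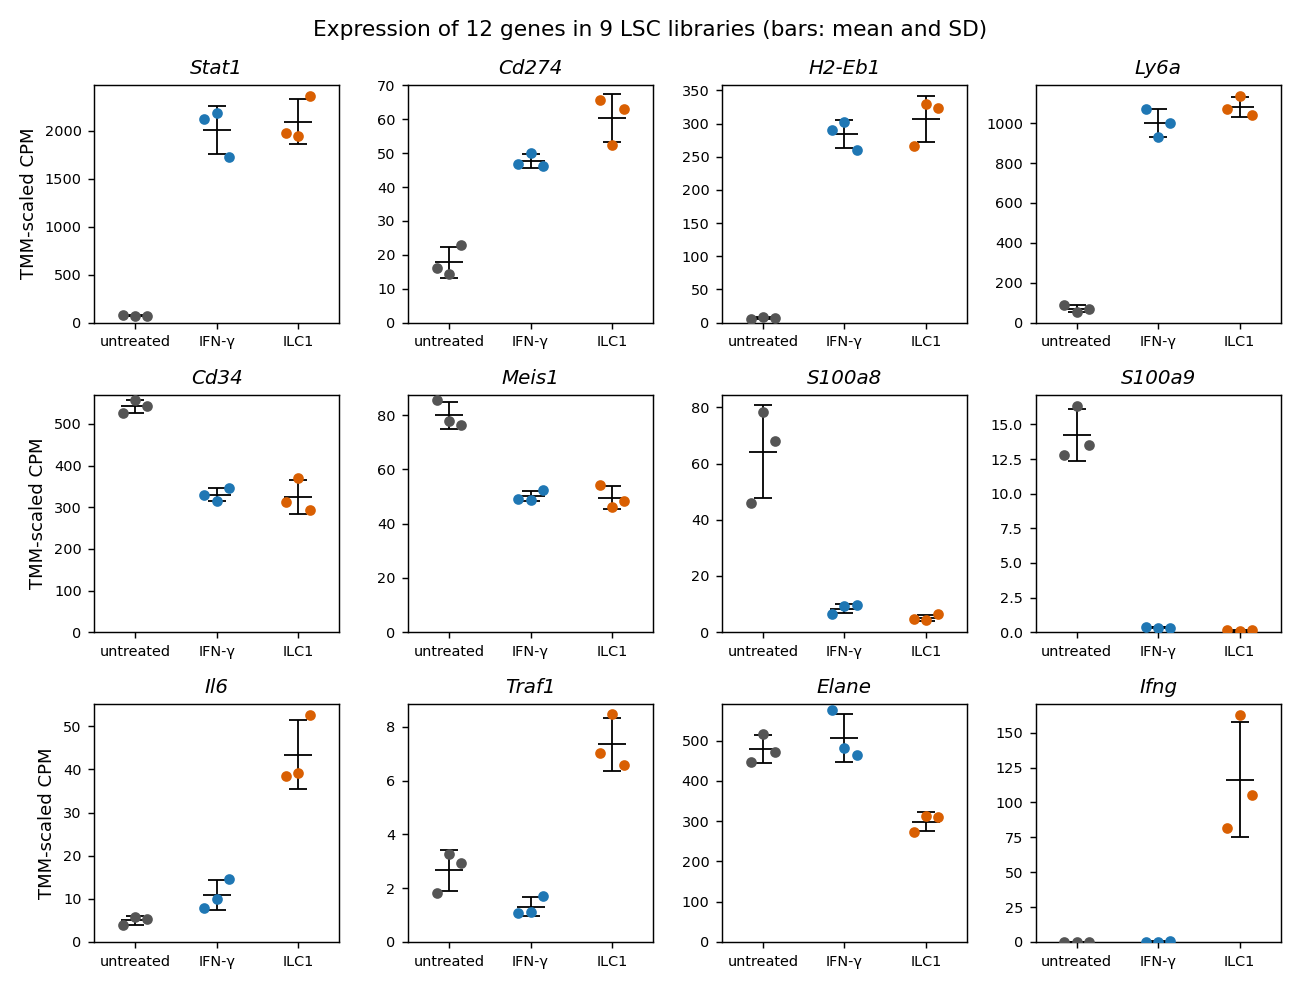
TMM-scaled CPM of 12 genes in the 9 libraries, 1 panel per gene with its own linear axis from 0; points are single libraries, and black marks give the mean ± SD of 3. Stat1 rose from a mean of 71.8 to 2013 with IFN-γ and 2097 after co-culture, Cd34 went from 542 to 330 and 326, Il6 reached 10.8 and 43.5, and Ifng averaged 116 there.

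After co-culture with ILC1s, with lymphocyte markers and genes under an average log2 CPM of 3 passed over, GTPases and chemokines were again among the largest rises. Iigp1 reached 808 ± 24.9 CPM (log2 fold change against untreated 9.06 ± 0.59, or 11.27 without untreated 1), Cxcl9 rose to 103 ± 14.3 CPM (8.27 ± 0.54), Cxcl10 to 463 ± 14.2 CPM (7.27 ± 0.34) and Cxcl11 to 37.5 ± 4.18 CPM (7.05 ± 0.19). Stat1 rose to 2097 ± 234 CPM (4.87 ± 0.12, edgeR adjusted p = 3.7e-11), with Irf1 (3.12 ± 0.11), Irf8 (2.32 ± 0.11), Socs1 (2.22 ± 0.07), Ciita (4.52 ± 0.18) and Cd274 (1.77 ± 0.15). Falls of genes at that level included S100a8 (-3.63 ± 0.24), the basophil protease Mcpt8 (-1.78 ± 0.22) and the stem cell surface protein Prom1 (-1.72 ± 0.18).

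Of the 45 IFN-γ response genes, 44 rose and 0 fell (44 adjusted over the list alone, camera adjusted p = 1.6e-42), and all 42 type I interferon-stimulated genes rose (42 adjusted over the list alone, camera adjusted p = 6.0e-33) with a median of 4.53. For the interferon-stimulated list the adjusted p was 0.0881 with an estimated correlation. In the MHC class I list 21 of 23 genes rose (21 adjusted over the list alone, camera adjusted p = 1.2e-23), and in the class II list 10 of 15 (10 adjusted over the list alone, camera adjusted p = 5.3e-10), with 0 falls in either. Psmb9 (2.56 ± 0.05), Tap1 (3.03 ± 0.07), H2-Eb1 (5.50 ± 0.12) and H2-Ab1 (5.16 ± 0.14) were among them. Cell death genes rose in 26 of 41 cases, with 3 falls, Casp6, Bcl2 and Diablo, named after their values were seen (28 and 3 adjusted over the list alone, camera adjusted p = 2.5e-10). Casp1 rose by 1.68 ± 0.07, Mlkl by 1.61 ± 0.07 and Fas by 1.27 ± 0.13. Of 33 JAK-STAT genes 17 rose and 2 fell, Jak3 and Socs2, named after their values were seen (18 and 4 adjusted over the list alone, camera adjusted p = 2.1e-04; adjusted p = 0.0972 with an estimated correlation).

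NF-κB and inflammatory genes rose in 25 of 35 cases, with 2 falls, Nfkb1 and Ccl17, named after their values were seen (26 and 5 adjusted over the list alone, camera adjusted p = 9.0e-10). Csf1, the macrophage growth factor, rose by 2.84 ± 0.11, the NF-κB inhibitor Tnfaip3 by 2.02 ± 0.11 and Tnf by 1.59 ± 0.11. Il6 rose from 5.0 ± 1.04 to 43.5 ± 8.01 CPM (3.12 ± 0.24), and the chemokines Ccl3 (2.58 ± 0.16) and Ccl4 (3.99 ± 0.30) rose as well. In the monocyte and macrophage list 17 of 29 genes rose and 0 fell (17 and 1 adjusted over the list alone, camera adjusted p = 3.6e-07). Ms4a6c (3.48 ± 0.14), Mpeg1 (3.50 ± 0.23) and Tlr2 (1.33 ± 0.08) were among them, and Spi1 rose by 0.39 ± 0.06. Granulocyte genes fell in 9 of 22 cases and rose in 4, Lcn2, Lyz2, Itgam and Padi4, of which Itgam and Padi4 were named after their values were seen (12 and 4 adjusted over the list alone, camera adjusted p = 0.013). The adjusted p of that list was 0.139 with an estimated correlation. S100a9 fell to 0.115 ± 0.0532 CPM (-6.90 ± 0.26), Chil3 fell by 3.79 ± 0.23, and the neutrophil protease Elane fell from 479 ± 35.0 to 299 ± 22.9 CPM (-0.68 ± 0.08).

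Of the 43 stem cell and MLL-type leukemia genes, 15 fell and 6 rose (19 and 7 adjusted over the list alone, camera adjusted p = 0.0035; adjusted p = 0.104 with an estimated correlation). Cd34 fell to 326 ± 40.7 CPM (-0.74 ± 0.08), Meis1 to 49.6 ± 4.21 CPM (-0.69 ± 0.07) and Sox4 to 56.2 ± 3.41 CPM (-0.87 ± 0.06), and Ly6a rose by 3.98 ± 0.16. Flt3 fell by 2.05 ± 0.47. Hoxa9 changed by -0.25 ± 0.10 (edgeR adjusted p = 0.080), which passed with scaling by library totals (adjusted p = 0.0289) and with the replicate number as a block (adjusted p = 0.0369). Mki67, a proliferation marker, changed by -0.34 ± 0.09 (edgeR adjusted p = 0.011), a call lost without ILC1 co-culture 2 (adjusted p = 0.0596) or 3 (adjusted p = 0.0510). Kit (0.16 ± 0.08), Myc (-0.07 ± 0.06), Mpo (0.01 ± 0.11), Cebpa (-0.19 ± 0.09), Il7r (-1.10 ± 0.67) and Ifngr1 (-0.18 ± 0.07) did not pass. Of these, Kit passed without untreated 2 (adjusted p = 0.0336), Ifngr1 passed without untreated 1 (adjusted p = 0.0164) and with library totals (adjusted p = 0.0254), and Myc passed with library totals (adjusted p = 0.0437).

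Transcripts of the ILC1 and NK cell list were present in the re-sorted co-culture libraries. Of the 31 tested genes of the ILC1 and NK cell list, 25 rose and 0 fell against untreated cells (25 and 1 adjusted over the list alone, camera adjusted p = 8.5e-14). With IFN-γ alone 7 rose and 1 fell, Nkg7, named after its value was seen (7 and 1 adjusted over the list alone). The list was called with IFN-γ alone too (camera adjusted p = 0.0275), but not with an estimated correlation (adjusted p = 0.442). Ifng averaged 116 ± 41.5 CPM after co-culture, with unscaled library values of 82.2, 162 and 102 CPM, and its ratio to the untreated libraries was 3585 (95% counting interval 1227 to 17390). The cytotoxic protease Gzma had 1486 counts after co-culture and 0 in the other 6 libraries, at least 411-fold higher than untreated and at least 472-fold higher than with IFN-γ, against a floor of 3 counts over each group. The IL-2 receptor chain Il2rb was 184-fold higher than untreated (105 to 357), the transcription factor Tbx21 20.8-fold (11.1 to 43.9) and the receptor Ncr1 53.5-fold (14.5 to 446). Klrb1c, which encodes the surface marker NK1.1, was not higher (ratio 0.649, 0.408 to 1.03), nor was the NK factor Eomes (ratio 0.691, 0.324 to 1.45). These intervals cover counting error only. Gzma, Il2rb, Tbx21, Ncr1, Klrb1c and Eomes are outside the naming rule. In the T cell list 5 of 10 genes rose, Cd3g, Cd247, Cd28, Lck and Zap70, and 1 fell, Ubash3a (5 and 1 adjusted over the list alone); the list was not called (camera adjusted p = 0.076), though it was with library totals (0.0288), with no count filter (0.00438) and without any 1 of 6 libraries (0.00828 to 0.0499), and Cd247 and Cd28 were named after their values were seen. Ubash3a lost its call without untreated 2 (adjusted p = 0.0550) or ILC1 co-culture 1 (adjusted p = 0.0583) or 3 (adjusted p = 0.0618). The NF-κB, monocyte and interferon-stimulated groups of this comparison rose in the same 3 libraries as these lymphocyte marker transcripts.

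Co-culture changed 3636 genes by edgeR's quasi-likelihood test, 2049 higher and 1587 lower (56.4% higher), with 615 rising and 200 falling at least 2-fold. The co-culture libraries did not overlap the untreated ones for 39.6% of the genes, against 10% by chance. Scaling by library totals alone gave 1663 higher and 2516 lower (39.8% higher), and without ILC1 co-culture 2 the falls numbered 1016 and the rises 1700. With an estimated correlation 7 of the 32 lists held: the IFN-γ response, MHC class I, MHC class II, cell death, monocyte and macrophage, ILC1 and NK cell, and NF-κB lists.

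Co-culture and IFN-γ alone were then compared directly. With lymphocyte markers and genes under an average log2 CPM of 3 passed over, the largest rises of co-culture beyond IFN-γ included inflammatory cytokines and chemokines. Passing over markers does not remove any other RNA of ILC1s, so these rises may not all lie in LSCs. Il6 was at 43.5 ± 8.01 CPM after co-culture and 10.8 ± 3.45 CPM with IFN-γ (log2 difference 2.01 ± 0.22, edgeR adjusted p = 0.0015), the neutrophil-attracting chemokine Cxcl2 at 18.8 ± 3.44 and 4.88 ± 0.456 CPM (1.95 ± 0.20), and Ccl3 at 307 ± 25.5 and 111 ± 11.2 CPM (1.47 ± 0.15). The IL-2 receptor α chain Il2ra (1.75 ± 0.23), the small GTPase Mras (1.65 ± 0.24), Cxcl11 (1.43 ± 0.12) and the oxidase Nox1 (1.24 ± 0.19) were also higher. Elane was lower, at 508 ± 59.6 CPM with IFN-γ and 299 ± 22.9 CPM after co-culture (-0.76 ± 0.08, edgeR adjusted p = 5.7e-04). Sorl1 (-0.56 ± 0.08) and Sema4a (-0.46 ± 0.06) were lower too, and Chil3, at a lower level of expression, differed by -1.12 ± 0.24.

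In the NF-κB and inflammatory list 11 of 35 genes were higher after co-culture than with IFN-γ and 0 lower (17 adjusted over the list alone, camera adjusted p = 1.2e-16). Traf1, an adaptor of TNF receptors, was at 7.36 ± 0.993 and 1.30 ± 0.353 CPM (2.49 ± 0.25), and Ebi3 (0.67 ± 0.07), Lta (4.10 ± 0.51) and Tnf (0.80 ± 0.11) were higher. Ccl4 differed by 2.10 ± 0.26 (edgeR adjusted p = 0.010), a call lost without IFNg 1 (adjusted p = 0.0657). Of 42 type I interferon-stimulated genes, 10 were higher and 0 lower (37 adjusted over the list alone, camera adjusted p = 3.1e-19), with a median of 0.88; for this list the adjusted p was 0.235 with an estimated correlation. Ifit3 (13.5 ± 3.94 and 2.98 ± 0.331 CPM), Phf11b (1.17 ± 0.18), Ifi204 (0.73 ± 0.12) and Oas1a (0.71 ± 0.11) were among the 10. In the IFN-γ response list 4 of 45 were higher, Cxcl11, Gbp9, Stat2 and Gbp3 (10 adjusted over the list alone, camera adjusted p = 4.9e-06; adjusted p = 0.270 with an estimated correlation). Of these 4, Gbp9, Stat2 and Gbp3 each lost the call without IFNg 1 (adjusted p = 0.0762, 0.111 and 0.0717) and without several other single libraries (adjusted p up to 0.131, 0.130 and 0.158), and Stat2 lost it with no count filter (adjusted p = 0.184) and Gbp9 in a fit of these 6 libraries alone (adjusted p = 0.0530). In the monocyte and macrophage list 6 of 29 genes were higher and 0 lower (9 and 1 adjusted over the list alone, camera adjusted p = 6.5e-04; adjusted p = 0.137 with an estimated correlation), including the receptor Cd14 (0.79 ± 0.11) and Ms4a4c (1.62 ± 0.24).

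ILC1 and NK cell genes were higher after co-culture than with IFN-γ in 16 of 31 cases and lower in 0 (22 adjusted over the list alone, camera adjusted p = 4.6e-25), with a median log2 difference of 2.35. Xcl1 was at 5.77 ± 2.02 CPM after co-culture and 0.0107 ± 0.0185 CPM with IFN-γ, Cxcr6 at 9.96 ± 3.54 and 0.146 ± 0.157 CPM, and Prf1 (perforin) at 5.25 ± 2.30 and 0.0394 ± 0.0345 CPM. Ifng differed by 9.64 ± 0.50. In the T cell list Zap70 and Lck were higher, 2 of 10 genes (6 adjusted over the list alone, camera adjusted p = 4.9e-05); Lck lost the call without IFNg 2 (adjusted p = 0.0697), IFNg 3 (adjusted p = 0.0847) or ILC1 co-culture 2 (adjusted p = 0.0908). In the granulocyte list Lyz2 (0.45 ± 0.06) and Lcn2 (0.91 ± 0.12) were higher and Elane, Mmp8 and Chil3 lower, 5 of 22 genes (3 higher and 11 lower adjusted over the list alone, camera adjusted p = 3.0e-04; adjusted p = 0.0797 with an estimated correlation). Mmp8 lost its call without IFNg 2 (adjusted p = 0.0648), ILC1 co-culture 1 (adjusted p = 0.0733) or ILC1 co-culture 3 (adjusted p = 0.0846).

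No gene of the MHC class I and II lists passed the edgeR test between the treatments: 0 of 38 at an adjusted p under 0.05 and 6 at an unadjusted p under 0.05, with a median difference of 0.04. H2-Ab1 differed by 0.10 ± 0.11 and B2m by 0.07 ± 0.07. Stat1 (0.06 ± 0.10), Irf1 (-0.01 ± 0.10), Ciita (0.12 ± 0.14), Ly6a (0.11 ± 0.14), Cd34 (-0.02 ± 0.08) and Meis1 (-0.02 ± 0.07) did not pass either. Nor did Cd274 (0.34 ± 0.14) or Fas (0.42 ± 0.13), which passed in a fit of these 6 libraries alone (adjusted p = 0.0303 and 0.0203); Fas also passed without untreated 3 (adjusted p = 0.0475). In the cell death list Tnf and Tnfrsf1b were higher, 2 of 41 genes (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0024; adjusted p = 0.0642 with an estimated correlation). Tnfrsf1b lost its call without IFNg 2 (adjusted p = 0.0517) or ILC1 co-culture 3 (adjusted p = 0.0507). Among the stem cell and MLL-type leukemia genes 1 of 43 was higher, Il2ra, and 0 lower (2 adjusted over the list alone, camera adjusted p = 0.87). Whether the Il2ra difference lies in the LSCs was not tested.

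Between the treatments 255 genes differed by edgeR's quasi-likelihood test, 204 higher and 51 lower after co-culture, with 72 higher and 2 lower at least 2-fold; the 2 were Chil3 and Nlrp6, Nlrp6 being named after its value was seen. The libraries did not overlap for 21.5% of the genes, against 10% by chance. The count fell to 119, 115 and 161 without IFNg 1, 2 and 3 and to 128 and 148 without ILC1 co-culture 2 and 3, and it rose to 381 without untreated 3. Over single libraries left out, the higher genes numbered 99 to 297 and the lower ones 16 to 89. DESeq2 called 552. With an estimated correlation 3 of the 32 lists held: the ILC1 and NK cell, T cell and NF-κB lists.

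The responses to both treatments were set against each other over the 13406 genes. Called genes that rose with both numbered 1340, or 85.8% of those that rose with IFN-γ, and genes that fell with both numbered 737, or 78.7% of those that fell. Independent lists of these sizes would share 239 and 111 genes, and 100 simulated pairs of unchanged groups against the same untreated libraries had 0.15 to 0.23 calls per treatment and direction and shared 0.02 on average, which sets no level for lists of these sizes. The untreated libraries are too few to be split between the comparisons, so part of the excess over independent lists may come from the shared controls. The log2 changes correlated across genes with r = 0.838 (simulated mean 0.510), and their covariance was 0.513 against a simulated 0.0527, a difference of 0.460, with the shared controls in both values. Genes called in opposite directions numbered 4: Traf1, which fell by 1.03 ± 0.26 with IFN-γ and was 1.46 ± 0.24 higher after co-culture, Basp1 (-0.43 ± 0.09 and 0.28 ± 0.09), Asb2 (-1.67 ± 0.54 and 2.22 ± 0.45) and Gimap3, which had 0 counts in the IFN-γ libraries. The last 3 were named after their values were seen. Whether the co-culture rises of these 4 genes lie in the LSCs was not tested.

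**Figure D2:**
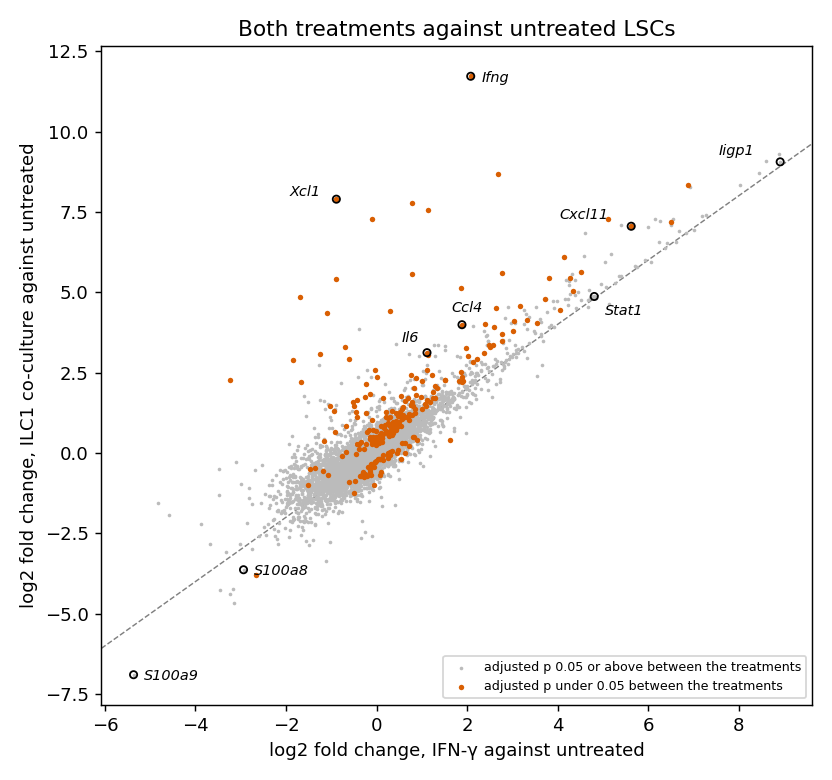
Log2 fold change of each gene with IFN-γ (horizontal) and after ILC1 co-culture (vertical), both against the untreated libraries, for 13393 tested genes; 13 genes with 0 counts in a group are left out. Orange points are genes whose edgeR adjusted p between the treatments was under 0.05, the dashed line marks equal change, and Ifng and Xcl1 stand far above it while Stat1 and Iigp1 lie near it.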

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

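Counting only genes of average log2 CPM of at least 2 was chosen after the data were seen; the other settings were fixed before. None of the 417 values of named genes or 96 list results changed direction past the threshold under the settings run for them. The direction of other genes was not followed gene by gene. With library totals alone the balance of called genes did reverse, to 1142 higher and 2184 lower with IFN-γ and 1663 and 2516 after co-culture. Leaving out single libraries gave 1668 to 2819 genes for IFN-γ (2499 with all), 2716 to 3852 for co-culture (3636) and 115 to 381 between the treatments (255), with 1498 to 2331 genes shared in direction (2077); lists called ranged over 16 to 21, 18 to 22 and 13 to 17. DESeq2 and the fit of 2 groups alone each called 552 genes between the treatments, with 252 and 248 of the 255 kept; the cause was not tested. The estimated correlation left 4, 7 and 3 lists of 21, 19 and 16. Calls were also lost where the estimate was below the preset 0.01, as for NF-κB genes with IFN-γ (0.0081). Members varying together therefore do not account for every loss. Between the treatments fry called 8, a test that does not set a list against other genes. Library totals alone moved the median change of all genes to -0.10 and -0.08. Genes of average log2 CPM of at least 2 gave 2379, 3396 and 221 calls. With the replicate number as a block, the calls were 2479, 3597 and 294. Same-numbered libraries deviated together with correlations of -0.19 to 0.26, and 6 of the 9 correlated best with their own number, a hint from the data and not from the design, where the samples share only a number. Of 353 called values of named genes, 62 lost the call without some library and 31 under some other setting, and 10 others gained it; of 56 list calls, 13 and 42 were lost, and 15 gained. Low counts limit small changes: simulated changes of 0.5 were recovered for 2 of 24, 2 of 35 and 6 of 35 genes with counts up to the median for IFN-γ, co-culture and between the treatments, and for 41 of 43, 29 of 32 and 31 of 32 genes above it, a split added after the data were seen.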

Other observations

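All tests of explanations in this part were chosen only after the results were seen; the gene lists and splits were fixed before. Cell cycle, growth and metabolic genes changed in smaller steps, by list counts that are given here without a claim for the lists, since none of their calls held with an estimated correlation. Of 34 G2/M genes, 20 fell and 0 rose after co-culture (26 lower adjusted over the list alone; adjusted p = 0.206 with an estimated correlation), among them Cdc20 (-0.60 ± 0.07) and Ccnb2 (-0.50 ± 0.06). With IFN-γ 10 fell and 1, Top2a, rose (12 and 1 adjusted over the list alone; adjusted p = 0.442 with an estimated correlation), and with scaling by library totals the falls numbered 28 and 21. Of 27 p53 targets, 16 rose after co-culture and 1, Ckap2, fell (19 and 2 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation), including Mdm2 (0.82 ± 0.10), Ccng1 (0.92 ± 0.12) and Bbc3 (1.37 ± 0.19); with IFN-γ Mdm2, Fas, Ccng1 and Tigar rose and Ckap2 fell (7 and 1 adjusted over the list alone; adjusted p = 0.523 with an estimated correlation). Between the treatments 0 G2/M genes were called (6 lower adjusted over the list alone) and 1 p53 target, Bbc3 (11 adjusted over the list alone), with adjusted p = 0.270 and 0.244 with an estimated correlation; Bbc3 lost the call without IFNg 1, 2 or 3, untreated 2, or ILC1 co-culture 1 or 2 (edgeR adjusted p 0.0635 to 0.169) and with no count filter (edgeR adjusted p = 0.109). Of 37 MYC targets and ribosome biogenesis genes, 24 fell after co-culture and 1, Max, rose. Adjusted over the list alone these were 26 and 1 (adjusted p = 0.225 with an estimated correlation). With IFN-γ there were 6 falls and 2 rises, Max and Polr1a, Polr1a being named after its value was seen. Adjusted over the list alone the IFN-γ counts were 7 and 2 (adjusted p = 0.523 with an estimated correlation). Library totals moved the IFN-γ count to 22 falls and 1 rise.

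Cholesterol biosynthesis genes rose in 13 of 24 cases with IFN-γ and 15 after co-culture, with 0 falls (15 and 19 adjusted over the list alone; adjusted p = 0.123 and 0.104 with an estimated correlation), among them Fdps (0.39 ± 0.06 and 0.44 ± 0.06) and Hmgcr (0.48 ± 0.06 and 0.43 ± 0.06). In the unfolded protein and ATF4 list 12 of 31 rose and Xbp1 fell with IFN-γ (14 and 2 adjusted over the list alone; adjusted p = 0.339 with an estimated correlation), and 18 rose and Xbp1 and Slc7a5 fell after co-culture (18 and 3 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation). Between the treatments Atf3 (1.07 ± 0.13), Trib3 (1.00 ± 0.12), Chac1 and Slc7a11 were higher and Xbp1 (-0.35 ± 0.06) and Slc7a5 lower (10 and 2 adjusted over the list alone; adjusted p = 0.648 with an estimated correlation); Chac1 and Slc7a11 were named after their values were seen, and Slc7a5 lost its call without IFNg 1 or 3 or ILC1 co-culture 2 or 3 (edgeR adjusted p 0.0580 to 0.0788). Glycolysis and hypoxia genes rose in 16 of 29 cases after co-culture with 0 falls (17 adjusted over the list alone; adjusted p = 0.30 with an estimated correlation), the hexokinase Hk3 by 1.83 ± 0.12, and in 6 with IFN-γ, where Slc2a3 and Ankrd37 fell (8 and 2 adjusted over the list alone; adjusted p = 0.623 with an estimated correlation), Slc2a3 being named after its value was seen. Immediate early and heat shock genes rose in 13 of 26 cases after co-culture and 1, Dnaja1, fell. Adjusted over the list alone these were 13 and 2 (adjusted p = 0.155 with an estimated correlation). Dnaja1 was named after its value was seen.

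The remaining lists are given as counts of genes higher and lower with IFN-γ and then after co-culture, with the estimated-correlation adjusted p of each. They were 6 and 3, then 6 and 4, of 40 PI3K-AKT-mTOR genes (0.687 and 0.702), with Akt3 at 1.60 ± 0.16 and 1.52 ± 0.16. They were 9 and 3, then 9 and 3, of 22 adhesion and homing receptors (0.339 and 0.30), with Itgb7 at 3.32 ± 0.16 and 2.95 ± 0.16. Of 30 checkpoint and NK-ligand genes 12 were higher and 4 lower after co-culture (0.512). Counts were 3 and 0, then 7 and 1, of 36 S phase genes (0.816 and 0.766), and 0 and 2, then 0 and 3, of 46 ribosomal protein genes (0.574 and 0.571). They were 0 and 0, then 0 and 3, of 40 oxidative phosphorylation genes (0.767 and 0.739), and 0 and 0, then 0 and 1, of 18 histone genes (0.816 and 0.709). Among lineage lists they were 2 and 2, then 5 and 4, of 21 dendritic cell genes (0.748 and 0.940), 2 and 7, then 5 and 9, of 26 lymphoid genes (0.123 and 0.431), and 0 and 3, then 0 and 1, of 6 mature B cell genes (0.123 and 0.256). They were 2 and 2, then 2 and 1, of 12 erythroid genes (0.748 and 0.702), 2 and 1 in both of 14 megakaryocyte genes (0.816 and 0.965), and 6 and 1, then 3 and 2, of 16 mast cell genes (0.523 and 0.669). T cell genes were 0 and 0 of 10 with IFN-γ (0.442), and immediate early genes 6 and 3 of 26 (0.523). Klrd1, which is on both the dendritic cell list and the ILC1 and NK cell list, was among the co-culture rises (7.27 ± 0.79). Whether the co-culture rises of the dendritic cell and lymphoid lists lie in the LSCs was not tested.

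In unscaled CPM, untreated 1 had Isg15 at 5.66 against 1.24 and 1.45 in the other untreated libraries, and Iigp1 at 3.96 against 0.177 and 0.530. Isg15 was named after its value was seen. Olfactory and vomeronasal receptor genes (1425), which LSCs are not known to use, summed to 41.5, 14.4 and 76.5 CPM in untreated 1, 2 and 3, and to 15.5 to 42.9 in the treated libraries.

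The ILC1 and NK cell transcripts in the co-culture libraries are the pattern most in need of a source. Of 27 list genes under 0.2 CPM in the untreated and IFN-γ libraries, 16 (59.3%) were higher in all 3 co-culture libraries than in all 6 others, against 1 of 35 silent genes (2.86%) in 6 lists of other lineages and 4 of 13 in the T cell list under the same filter, so ILC1s or their RNA carried through the re-sort may be the source. Klrb1c (NK1.1), too high in untreated cells for that filter, did not go with this. It was at 0.504, 0.083 and 0.355 CPM in co-cultures 1, 2 and 3, against 0.490 untreated and 0.241 with IFN-γ. IFN-γ acting on the LSCs as strongly as when given alone was argued against as the only source, because 16 of the 25 list genes that rose were higher in co-culture than with IFN-γ alone. A stronger IFN-γ signal stays open for the 13 of these that did not rise with IFN-γ alone. Their lowest log2 difference between the treatments was 3.26 (Klrk1, 2.09 less 2 SE). The highest of the 45 IFN-γ response genes, Nos2, differed by 1.51. The 13 were chosen for passing the test of that same difference, so their lowest value is partly set by the choice. The response genes may also be saturated. A stronger signal stays open as well for the other 3 (Gzmb, Ccl5 and Fcer1g, median difference 1.60), which also rose with IFN-γ alone. Klrk1, Nos2, Gzmb and Ccl5 were named after their values were seen. Of the 9 that did not pass the test between the treatments, 4 (Itga1, Tnfsf10, Il18rap and Il12rb2) also rose in the IFN-γ libraries, which held no ILC1s, so carry-over is not needed for them. The other 5 were not called as rising with IFN-γ alone (differences between the treatments of 1.97 to 2.81, median 2.35, edgeR adjusted p over all genes 0.0877 to 0.194). Adjusted over the list alone, 22 list genes were higher in co-culture than with IFN-γ. For these 5 carry-over and IFN-γ cannot be told apart, because a stronger IFN-γ signal would also leave them higher in co-culture.

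The excess of NF-κB and interferon-stimulated genes in co-culture over IFN-γ alone could come from carried-over ILC1s, from a stronger IFN-γ signal, or from a response of LSCs to other ILC1 signals. Co-culture 2 held more of the silent ILC1 and NK transcripts than co-cultures 1 and 3, with a median log2 ratio of excess of 0.68 over 11 genes (0.26 to 1.23), while the 11 higher NF-κB genes had a median ratio of -0.14 (-0.90 to 0.39). The same ratios of co-cultures 1 and 3 had medians of -0.01 and 0.15 for NF-κB genes, inside the ranges of the silent genes (-0.97 to 0.33 and -1.13 to 0.26), so a single library carries the contrast and carry-over and response cannot be told apart. The 10 higher interferon-stimulated genes had a median of 0.55 (0.21 to 0.75) in co-culture 2, inside the range, and cannot be told apart either. A stronger IFN-γ signal stays open: the MHC genes were level between the treatments (median 0.0413), which saturation would also give, while 4 of the 11 NF-κB genes did not rise with IFN-γ alone and Traf1 fell with it (-1.03 ± 0.26); a response to other ILC1 signals was not tested.

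S100a8, S100a9 and Chil3 fell with both treatments. The smallest of the folds by which untreated exceeded a treated group was 6.69 (Chil3 with IFN-γ, where S100a8 had 8.10 and S100a9 44.3). The silent receptor genes had a 4.95-fold range from the highest untreated to the lowest treated library. This argues against background reads of the kind the receptor genes gauge. Stray neutrophil RNA need not follow the receptor genes, so it was not tested as a cause. Fewer mature granulocytes among the treated cells may be a cause; the other 19 granulocyte genes had a median change of 0.10 with IFN-γ, 4 higher and 2 lower, and of -0.19 after co-culture, 4 higher and 6 lower, which cannot settle it because LSCs express many of them. A direct effect of IFN-γ on these genes was not tested.

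Splits of 6 libraries into 3 and 3 number 10, so no share under 0.1 is possible. Every split but the real one mixed the compared groups, so changes between the groups entered the spread within each side. The counts of those splits therefore set no chance level, for genes or for lists. For genes the real split called 2499 with IFN-γ against at most 0 in any other split, 3636 after co-culture against at most 0, and 255 between the treatments against at most 1, each count reached by 1 of 10 splits. For lists the real split called 21 against at most 14 (1 of 10), 19 against at most 19 (2 of 10) and 16 against at most 11 (1 of 10), and the split that tied put untreated 1 and 2 with ILC1 co-culture 1.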
